A study of Homo sapiens with 18 samples.

How the data were processed

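RNA from cultured BJ cells, a human skin fibroblast line, was measured in 18 libraries that form 6 groups of 3. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A)-bearing RNA was selected, and the heat-fragmented mRNA was reverse-transcribed from random hexamers. An adaptor was ligated to the single-stranded cDNA, which was amplified by 18 cycles of PCR and sequenced in paired-end reads on a DNBSEQ-T7 instrument. No molecular identifiers are described, so PCR copies of a fragment count separately, and counting intervals given for rare transcripts cover counting error only. The labels name the molecule as genomic DNA, which goes against their RNA protocol, and the protocol was followed here.

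The authors deposited read counts per gene in 2 tables, a knockdown table and an overexpression table of 9 libraries each, and each table lists 61544 genes with position, strand, type and the whole gene span. Per the submitters' processing notes, the tools named are FastQC 0.11.9, cutadapt 3.3, HISAT2 2.1.0, SAMtools 1.11, Subread, featureCounts 2.0.1 and DESeq2 1.34.0, and the builds named are hg38 and GRCh38.p13. The annotation release, the strand setting of the counting and the handling of reads with several placements are not given in the sources used here. The values were whole numbers with a different total in each library, that is, raw counts without normalization. In 20468 of the 61544 entries the gene name is only an Ensembl identifier.

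How reads were assigned to overlapping genes was looked up in the counts. All 9429 genes whose span lies inside another gene on the same strand had 0 counts in all 18 libraries, among them 638 protein-coding genes. Of the 11533 genes that lie only inside a gene on the opposite strand, 45% had counts, against 51.1% of the 22705 genes that overlap no other gene. Among protein-coding genes these shares were 79.7% of 1165 and 84.8% of 6701. Counts therefore followed the strand, and reads that fall on 2 genes of the same strand were not counted. A gene nested in a same-strand neighbour cannot be measured in these tables, and a gene that partly overlaps such a neighbour loses the reads of the overlap and is uncertain. Of the 565 entries of the gene lists that were in the tables, 3 were nested in this way (TIGAR, ALDOC and SDHA) and 149 partly overlapped a same-strand gene. Counts were 0 in all libraries for 17 entries, these 3, 12 of the partly overlapping ones and 2 others, so more members than the nested ones had no measurement; why the others had 0 counts was not tested.

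Samples were grouped by their titles into sgCtrl, sgPURPL-1 and sgPURPL-2 (a control guide and 2 guides of CRISPR interference, in which a guided repressor lowers transcription of its target) and Ctrl, PURPL-OE-1 and PURPL-OE-2 (a control and 2 cultures that overexpress PURPL, called lines here, since the labels do not say whether they are separate lines, constructs or clones). In the overexpression table, 5 columns carry no replicate number, 3 of line 1 and 2 of line 2, and entered as unnumbered libraries of their group. Columns left unused numbered 0. Total counts per library ran from 11444513 to 12896040 in the knockdown table and from 18858976 to 27985649 in the overexpression table. Whether changes in rare genes were easier to detect in the latter was not tested.

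Each table was fitted on its own with R 4.3.3. Genes were kept by edgeR's filterByExpr with the groups (min.count 10, min.total.count 15), library sizes were scaled by TMM, and edgeR 4.0.16's quasi-likelihood test with robust dispersion was run on all 9 libraries of the table, which share 1 estimate of the spread with 6 residual degrees of freedom. The contrasts were each guide against sgCtrl, each overexpression line against Ctrl, guide 2 against guide 1 and line 2 against line 1. P-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05, and every adjusted p of a single gene comes from this test. A joint fit of all 18 libraries tested whether the mean effect of both guides differed from the mean effect of both overexpression lines. Each table has its own control, so a difference between the tables that shifts all 3 groups alike cancels in that contrast. Levels are TMM-scaled CPM, the counts of a gene relative to the scaled total of its library. Outside the joint fit, which scaled all 18 libraries together, the tables were normalized separately. Levels set side by side across them also carry any difference between the experiments.

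A total of 25 gene lists was fixed before the data were examined, as were the tests, the alternatives and the rule for named genes; later additions are named where they appear. The lists were p53 targets, inflammatory secreted factors of senescence, proteases, inhibitors and growth factors of the senescence secretome, DNA replication, mitosis, fibrillar collagens and matrix, contractile and TGF-beta responsive genes, interferon response, cholesterol synthesis, the unfolded protein and amino acid stress response, the oxidative stress response (NRF2), lysosome, glycolysis and hypoxia, cytosolic ribosomal proteins, ribosome biogenesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, immediate early genes, heat shock, replication-dependent histones, fibroblast identity, and markers of keratinocytes, melanocytes, endothelial cells and immune cells. Lists were tested with camera (limma 3.58.1), which compares a list with all other genes, at its preset correlation between genes of 0.01, with adjustment over all lists and the 4 contrasts against control. Lists with fewer than 5 tested genes were not tested, which left 22 lists in the knockdown table and 23 in the overexpression table. Each test was repeated with a correlation estimated from the data, and 25 of the 41 calls among 90 tests held in it. The number of members past the threshold is given over all genes tested and again adjusted over the list alone. Where a list median carries an SE, this is the scaled median absolute deviation of its genes divided by the square root of their number. It treats genes as independent, which they are not, and does not measure the spread between libraries or experiments.

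Genes named are PURPL; a panel of 21 senescence genes; for each table the 10 genes with the highest and the 10 with the lowest mean change of both arms that passed in both, had a mean of at least 1 CPM and a gene symbol, and had all 6 treated libraries on the same side of the 3 controls; up to 4 members of each list that passed in at least 1 contrast; up to 10 genes called in opposite directions by knockdown and overexpression and up to 5 called alike in all 4 contrasts; and the 5 highest and 5 lowest differences between the arms of each table. Any other gene is named as chosen after its values were seen. A few genes that this rule names are not reported here. Genes with 3 or fewer counts over a group are given as a ratio of summed counts with an exact 95% interval, and where a group had 0 counts the ratio is a lower bound against 3 counts over the group.

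The fits were tested on simulated data drawn from the means and library sizes of the real genes, with 200 genes changed. For guide 1 against its control, on 13923 genes in 5 simulations, the test recovered 36.3% of changes of 1.25-fold, 73.1% of 1.5-fold, 85% of 2-fold and 97.2% of 4-fold, and 6.77% of its calls were false. For overexpression line 1, on 15267 genes, it recovered 38.7%, 68.3%, 82.6% and 97.6%, with 7.76% false calls. For the joint contrast, on 15166 genes in 2 simulations, it recovered 24.5%, 61.6%, 69.1% and 90.8%, with 5.49% false calls. The real contrasts called far more than 200 genes, so these rates need not carry over to them. Camera called 2 of 200 random lists of 25 genes and called a list shifted by 1.5-fold. Genes were drawn independently of each other there, so this check does not cover lists whose members vary together.

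Alternatives were DESeq2's size factors in place of TMM, no filter beyond 1 count, DESeq2 1.42.0's Wald test, fits on only the 2 groups compared, a 2-fold threshold, leaving out each library in turn, a rotation test (fry) for the lists, genes above 10 CPM for the correlation between tables, and the replicate number as a block. The block was fitted for the knockdown table alone. Alternatives restricted to genes with no same-strand overlap, and the correlation without the interferon list, were chosen after seeing the data.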

Results

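Gene expression was measured by poly(A) RNA sequencing in BJ human skin fibroblasts in which the long noncoding RNA PURPL had been lowered or raised. The series concerns the part of PURPL in cellular senescence, a lasting exit from the cell cycle that comes with secretion of inflammatory factors. In the knockdown experiment, CRISPR interference with 2 guides against PURPL (sgPURPL-1 and sgPURPL-2, here guides 1 and 2) was compared with a control guide (sgCtrl). In the overexpression experiment, 2 lines (PURPL-OE-1 and PURPL-OE-2, here lines 1 and 2) were compared with their own control (Ctrl). The labels do not say whether PURPL-OE-1 and PURPL-OE-2 are separate lines, constructs or clones, and the word line is used here only as a name. Each group held 3 libraries, 18 in all, with 11444513 to 12896040 counts per library in the knockdown table and 18858976 to 27985649 in the overexpression table.

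By correlation, replicates resembled each other more than they resembled other groups. Across genes, the correlation of log2 CPM was 0.99 to 0.993 between libraries of the same group in either table, and 0.979 to 0.989 (knockdown) or 0.971 to 0.989 (overexpression) between groups. No pair of libraries differed by as little as sampling noise, the lowest chi-square per gene being 2.47 in the knockdown and 3.53 in the overexpression table. In the knockdown table it reached 10.65 within a group (sgCtrl replicates 1 and 3) and began at 7.87 between groups, so the ranges overlapped. In the overexpression table it reached 8.77 within groups and began at 13.5 between them. The first principal component held 39.8% of the variance in the knockdown table and 53.2% in the overexpression table and parted the controls from both arms. The next component parted the 2 arms, with 18.1% and 13.8%. Mitochondrial transcripts took 4.46% to 5.14% of counts in the sgCtrl libraries and 4.78% to 5.45% with the guides, and 4.26% to 4.80% in Ctrl against 4.97% to 6.24% in the overexpression lines. The 10 most abundant genes took 7.88% to 8.24% of counts in Ctrl and 9.56% to 9.89% in the lines, so both shares moved with overexpression. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

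PURPL itself was checked first in every library. The gene (ENSG00000250337.8, a long noncoding RNA) lies on the plus strand of chromosome 5 from 27217714 to 27496994 in the hg38 coordinates of the tables, a span of 279281 bp. It measured 71.1, 77.0 and 94.3 CPM in the sgCtrl libraries, 17.9, 15.2 and 14.1 CPM with guide 1, and 19.0, 21.5 and 17.9 CPM with guide 2. The log2 fold change was -2.36 ± 0.104 (SE, adjusted p = 2.48e-15) for guide 1 and -2.06 ± 0.101 (adjusted p = 2.25e-14) for guide 2, which leaves 19.5% and 24.1% of the control level. The guides differed from each other by 0.30 ± 0.119 (adjusted p = 0.128), which did not pass. In the overexpression table PURPL measured 67.3, 66.7 and 59.2 CPM in Ctrl, 166, 178 and 176 CPM in line 1, and 125, 129 and 114 CPM in line 2. It rose 2.69-fold in line 1 (log2 1.43 ± 0.0590, adjusted p = 1.85e-18) and 1.9-fold in line 2 (0.93 ± 0.0594, adjusted p = 8.54e-14), and line 2 lay below line 1 by a log2 difference of -0.50 ± 0.0571 (adjusted p = 1.81e-07). The PURPL levels therefore parted the targeted libraries from their controls as the labels say. They are no check of which guide a library received, nor of which sample an unnumbered column holds. Of 12 other annotated genes within 1 Mb of PURPL, 0 had enough counts to be tested in either table, the highest total over 9 libraries being 8 counts, so effects on neighbouring genes were not detectable at this depth.

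**Figure D1:**
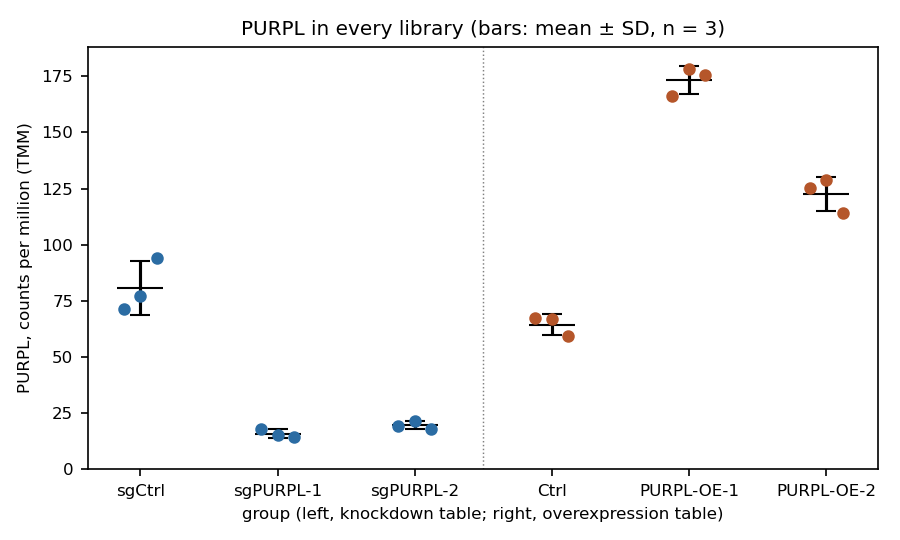
PURPL level in TMM-scaled CPM (vertical axis) in each of the 18 libraries (points), with the mean and SD of each group of 3 (bars). All 6 knockdown libraries lie at or below 21.5 CPM and all 6 overexpression libraries at or above 114 CPM, while the controls lie between 59.2 and 94.3 CPM; the 2 tables were normalized separately.

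Knockdown of PURPL was followed by lower expression of cell division genes with both guides. All 34 measured members of the mitosis list fell with guide 1 and 32 of 34 with guide 2, and of 34 DNA replication genes 29 fell with guide 1 and all 34 with guide 2. MKI67, the proliferation marker Ki-67, went from 283 ± 52.5 CPM (SD, n = 3) to 141 ± 3.52 and 178 ± 1.60 CPM. Over the same comparison the oxidative stress and interferon lists rose, and the elastin gene ELN went from 55.8 ± 2.66 to 275 ± 12.2 and 422 ± 3.51 CPM. In edgeR's quasi-likelihood test, 3417 of 13923 genes changed with guide 1 (1617 up, 1800 down) and 3393 with guide 2 (1663 up, 1730 down), or 24.5% and 24.4% of genes tested. At least a 2-fold change was found for 481 of these genes with guide 1 (229 up, 252 down) and 432 with guide 2 (292 up, 140 down).

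The guides shared 2076 of these genes with the same direction (948 up, 1128 down), and 34 genes passed in opposite directions. Independent lists of these sizes, with every gene equally likely to be called, would share 193 genes up and 224 down. In 5 simulations all 9 libraries, controls included, were drawn from the control means, so that both arms were unchanged and shared a control group. The arms shared a mean of 0.2 genes and at most 1. Unchanged arms call few genes, so this count was bound to lie near 0 and is no measure for the 2076. Across genes, which are not independent replicates, the fold changes of the guides correlated at 0.737, against 0.498 in the simulation. Their covariance was 0.135 against a simulated 0.0155, a difference of 0.12. Because 3 control libraries cannot be split, part of the excess may come from the shared controls.

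The mitosis list, kinases and spindle proteins that carry cells through division, had a median log2 fold change of -0.93 with guide 1 and -0.54 with guide 2 (camera adjusted p = 1.43e-58 and 1.47e-22, 4.21e-05 and 4.79e-04 with an estimated correlation). Adjusted over the list alone, 34 and 33 members fell. ANLN, a scaffold of the cleavage furrow, changed by log2 values of -1.23 ± 0.0646 and -0.67 ± 0.0634, TOP2A, which untangles DNA before division, by -0.86 ± 0.0602 and -0.56 ± 0.0596, and CDK1, the kinase that starts mitosis, by -0.93 ± 0.0875 and -0.79 ± 0.0864. The DNA replication list had medians of -0.54 and -0.59 (adjusted p = 2.11e-18 and 2.06e-24, 5.64e-04 and 4.40e-04 with an estimated correlation), and 30 and 34 members fell adjusted over the list alone. RRM2, a subunit of the enzyme that makes deoxynucleotides, went from 106 ± 5.72 to 47.4 ± 1.65 and 48.7 ± 1.248 CPM (adjusted p = 1.79e-14 and 3.85e-14). UHRF1, a factor of maintenance DNA methylation, changed by -0.98 ± 0.0901 and -1.15 ± 0.0915, and MCM10, a factor of replication start, by -1.28 ± 0.163 and -1.40 ± 0.166.

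The oxidative stress list, targets of the transcription factor NRF2, rose with both guides. Of 20 measured members, 19 rose with guide 1 and 13 with guide 2, and 0 fell (adjusted over the list alone, 19 and 14 rose), with medians of 0.54 and 0.45 (adjusted p = 7.35e-24 and 5.86e-10, 4.79e-04 and 0.00279 with an estimated correlation). SLC7A11, the cystine importer, went from 64.9 ± 9.70 to 161 ± 3.49 and 151 ± 12.5 CPM (adjusted p = 1.20e-12 and 5.96e-12). TXNRD1, a thioredoxin reductase, changed by 0.86 ± 0.0554 and 0.89 ± 0.0554, HMOX1, heme oxygenase, by 0.88 ± 0.0805 and 0.83 ± 0.0808, and the quinone reductase NQO1 by 1.16 ± 0.0622 and 0.48 ± 0.0624. Of 25 interferon response genes, 12 rose with guide 1 and 20 with guide 2 and 0 fell, the same numbers adjusted over the list alone, with medians of 0.25 and 0.45 (adjusted p = 1.93e-05 and 6.26e-21, 0.0106 and 4.79e-04 with an estimated correlation). BST2, a membrane tether of viruses, went from 24.4 ± 3.73 to 53.1 ± 4.41 and 44.1 ± 4.05 CPM. IFI44L changed by 0.64 ± 0.0631 and 1.09 ± 0.0624, and IFIT2 by 0.53 ± 0.0667 and 1.22 ± 0.0663.

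The unfolded protein and amino acid stress list rose in 13 of 24 members with each guide (14 and 15 adjusted over the list alone) and fell in 1 with guide 1. Its median was 0.27 with guide 1 (adjusted p = 1.08e-05, but adjusted p = 0.109 with an estimated correlation) and 0.37 with guide 2 (adjusted p = 4.46e-10, 0.0344 with an estimated correlation). DDIT4, an inhibitor of mTOR signalling, changed by 0.87 ± 0.0946 and 1.09 ± 0.0931, and PSAT1, an enzyme of serine synthesis, by 0.64 ± 0.0703 and 0.75 ± 0.0699. Of 19 glycolysis and hypoxia genes, 11 fell and 1 rose with each guide (adjusted over the list alone, 11 fell and 2 rose with guide 1, 12 fell and 1 rose with guide 2), with medians of -0.21 and -0.19 (adjusted p = 5.08e-04 and 7.57e-04, 0.0259 and 0.0274 with an estimated correlation). LDHA, lactate dehydrogenase, went from 1146 ± 34.8 to 731 ± 3.32 and 855 ± 34.2 CPM, and PDK1, which restrains pyruvate oxidation, changed by -0.55 ± 0.0863 and -0.69 ± 0.0874. Among genes with no same-strand overlap, an alternative chosen after seeing the data, the glycolysis call was lost for guide 2 (adjusted p = 0.114).

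Lists of matrix and contractile genes gave mixed results between the guides. The contractile and TGF-beta list rose with guide 2 in 8 of 17 members and fell in 2 (9 and 3 adjusted over the list alone), with a median of 0.17 (adjusted p = 6.17e-04, 0.0274 with an estimated correlation). With guide 1, 4 rose and 7 fell (4 and 10 adjusted over the list alone) with a median of -0.18 (adjusted p = 0.034, but adjusted p = 0.116 with an estimated correlation). That call was also lost without guide 1 replicates 2 or 3 (medians -0.19 and -0.17, adjusted p = 0.0589 and 0.055). TGFBI, a matrix protein induced by TGF-beta, rose by 0.66 ± 0.0779 and 1.20 ± 0.0762 and the inhibitor SMAD7 by 0.90 ± 0.126 and 1.19 ± 0.122, while the matricellular gene CCN1 changed by -1.003 ± 0.0583 and -0.45 ± 0.0573. The collagen and matrix list rose in 10 and 13 of 25 members and fell in 4 and 5 (adjusted over the list alone, 10 and 13 rose and 5 and 6 fell), with medians of 0.09 and 0.17. Its adjusted p was 6.89e-05 and 2.93e-05, but adjusted p = 0.136 and 0.121 with an estimated correlation. The proteoglycan gene VCAN rose by 1.66 ± 0.140 and 2.28 ± 0.134.

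Among the other lists, 11 of 20 cholesterol synthesis genes rose with guide 1 and 0 fell (11 and 2 adjusted over the list alone; median 0.21, adjusted p = 0.00205, but adjusted p = 0.0893 with an estimated correlation), and guide 2 did not pass (median -0.06, adjusted p = 0.409). Replication-dependent histone genes, whose few poly(A)-bearing transcripts are what this protocol reads, rose with guide 1 in 5 of 11 members (7 adjusted over the list alone; median 0.38, adjusted p = 6.74e-05, 0.0226 with an estimated correlation) and did not pass with guide 2 (median 0.11, adjusted p = 0.0777). H2BC4 rose by 0.92 ± 0.0870 and 0.64 ± 0.0886. Immediate early genes had 8 of 18 members down and 1 up with guide 1 (9 and 1 adjusted over the list alone; median -0.24, adjusted p = 0.0204, but adjusted p = 0.426 with an estimated correlation). That call was lost without sgCtrl replicate 1 (median -0.21, adjusted p = 0.0694), and guide 2 did not pass (median -0.21, adjusted p = 0.302). Lysosome genes had 8 of 23 members down and 1 up with guide 2 (9 and 1 adjusted over the list alone; median -0.15, adjusted p = 0.043, but adjusted p = 0.372 with an estimated correlation). The call was lost without sgCtrl replicate 2 (median -0.13, adjusted p = 0.0841) or guide 2 replicates 2 or 3 (medians -0.13 and -0.13, adjusted p = 0.0755 and 0.0569), and guide 1 did not pass (median -0.06, adjusted p = 0.678).

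Neither the secretome lists nor the p53 targets passed with both guides. Of 29 p53 targets 7 rose and 0 fell with guide 1 and 5 rose and 2 fell with guide 2 (adjusted over the list alone, 6 and 0, then 5 and 2), with medians of 0.08 and 0.06 (adjusted p = 0.132 and 0.557). Of 13 inflammatory secreted factors 5 rose and 2 fell with each guide (adjusted over the list alone, 6 and 2, then 8 and 2), with medians of 0.21 and 0.34 (adjusted p = 0.781 and 0.678). The chemokine gene CXCL8 rose from 0.477 ± 0.272 to 1.70 ± 0.103 and 2.00 ± 0.428 CPM, whereas the cytokine gene IL1B fell from 7.95 ± 1.10 to 3.48 ± 0.539 and 3.64 ± 0.389 CPM and PTGS2, a prostaglandin synthase, changed by -1.57 ± 0.0870 and -1.34 ± 0.0854. Proteases, inhibitors and growth factors of the secretome had 8 members up and 10 down of 23 with guide 1, and 6 up and 12 down with guide 2 (adjusted over the list alone, 9 and 11, then 7 and 13). The medians were -0.11 and -0.24, with adjusted p = 0.034 for guide 1, but adjusted p = 0.161 with an estimated correlation, and 0.11 for guide 2. The guide 1 call was lost without guide 1 replicates 1 or 3 (medians -0.09 and -0.13, adjusted p = 0.0575 and 0.0668). Within this list the collagenase gene MMP1 changed by 0.56 ± 0.0601 and 0.77 ± 0.0600 and the plasminogen activator gene PLAT by -1.54 ± 0.0655 and -1.24 ± 0.0645.

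The other lists of the knockdown table did not pass with either guide. Medians with guides 1 and 2 were 0.04 and -0.09 for cytosolic ribosomal proteins (adjusted p = 0.678 and 0.134), -0.02 and -0.00471 for ribosome biogenesis (0.622 and 0.959), and -0.01 and -0.04 for oxidative phosphorylation (0.882 and 0.757). They were 0.05 and -0.07 for mitochondrially encoded genes (adjusted p = 0.627 and 0.742), -0.03 and -0.04 for heat shock (0.742 and 0.702), 0.01 and -0.09 for fibroblast identity (0.44 and 0.423), and -0.13 and -0.19 for keratinocyte markers (0.517 and 0.742). With guide 1, the heat shock list had a mean of 0.07 against its negative median, and the camera direction of the oxidative phosphorylation list was up against its negative median.

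**Figure D2:**
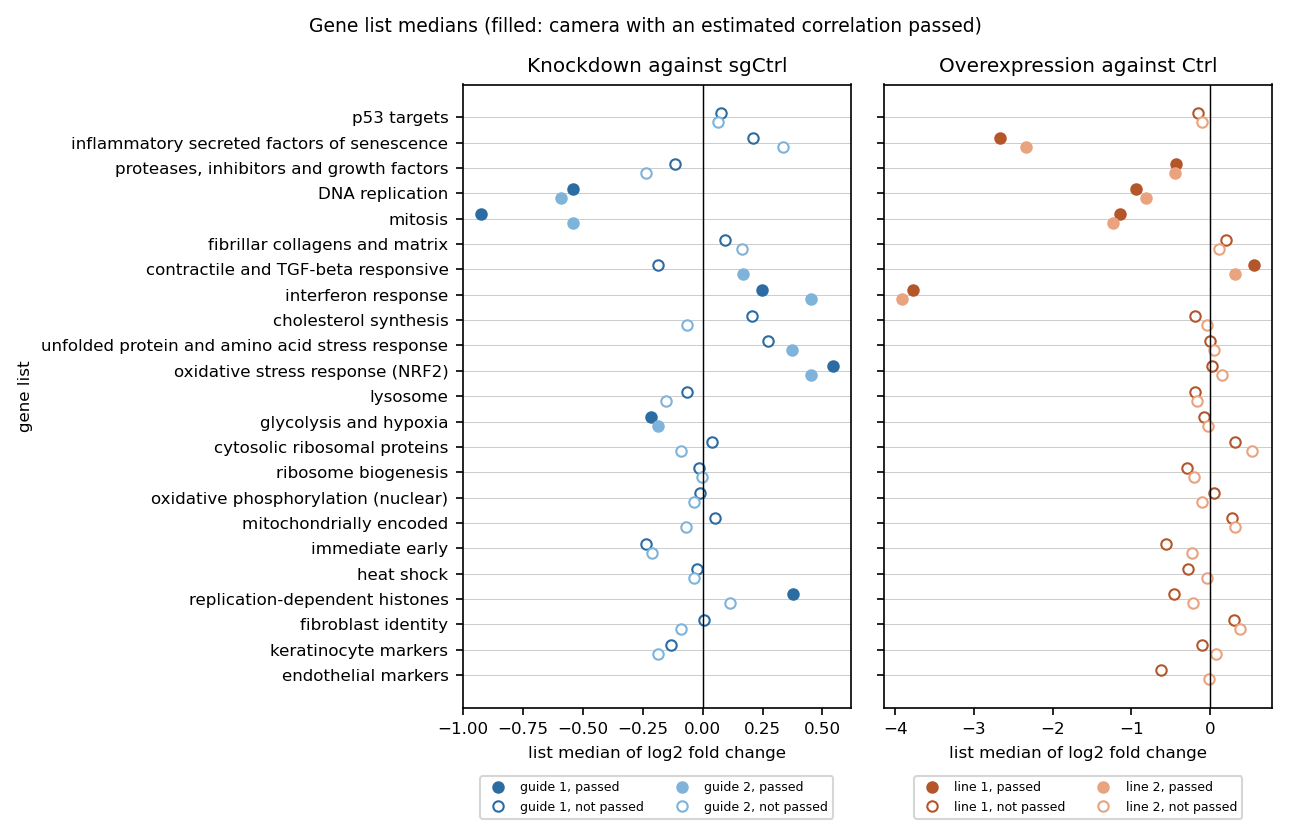
Median log2 fold change of each tested gene list (horizontal axis) for the guides against sgCtrl (left) and the overexpression lines against Ctrl (right), with filled points where camera passed with an estimated correlation. The mitosis and DNA replication lists lie below 0 in all 4 contrasts, and the interferon response list lies above 0 with both guides and at -3.78 and -3.92 in the lines.

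Single genes with larger changes than these lists were ranked by the mean change of both guides. The lowest besides PURPL were C10orf105, from 3.08 ± 0.336 to 0.133 and 0.272 CPM, and GABBR2, a subunit of the GABA-B receptor, from 40.4 ± 3.38 to 3.97 ± 0.145 and 10.2 ± 1.07 CPM (adjusted p = 2.51e-19 and 3.00e-15). They were followed by RGCC (-2.72 ± 0.345 and -2.49 ± 0.334), CNGA3, TEX29, MBP, TMEM158, SYT7 and LOXL4, a lysyl oxidase that crosslinks matrix, which went from 309.5 ± 13.5 to 75.5 ± 4.56 and 90.6 ± 0.421 CPM. The highest was DLX3, a homeobox gene with 1 count over the 3 sgCtrl libraries and 76 and 97 counts with guides 1 and 2. Its ratio to control was 76.4 (95% counting interval 13.3 to 3060.0) and 97.9 (17.2 to 3910.0). SAMD11 went from 0.800 ± 0.255 to 11.8 ± 1.10 and 13.4 ± 2.49 CPM, and DUSP2, POSTN, LINC02593, LHX8, KCNIP4 and SLITRK6 rose by log2 changes of 1.95 to 3.66. ELN rose by 2.30 ± 0.0633 and 2.92 ± 0.0639 (adjusted p = 8.08e-22 and 5.64e-25). ID1, an inhibitor of differentiation that responds to BMP signalling, went from 19.95 ± 4.12 to 96.2 ± 3.17 and 109 ± 6.65 CPM (adjusted p = 3.64e-16 and 6.54e-17).

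The fixed senescence panel moved in more than a single direction with knockdown. LMNB1, the lamin B1 gene that is lost in senescent cells, fell from 18.3 ± 1.09 to 11.1 ± 0.484 and 8.99 ± 1.16 CPM (adjusted p = 1.13e-05 and 5.35e-08), and MKI67 changed by -1.0002 ± 0.0973 and -0.67 ± 0.0961 (adjusted p = 9.61e-07 and 7.68e-05). CCNB1 (-0.81 ± 0.0701 and -0.37 ± 0.0683) and MCM2 (-0.55 ± 0.0832 and -0.62 ± 0.0837), a mitotic cyclin and a replication helicase subunit, also fell. The cell cycle inhibitor CDKN2B (p15) rose by 0.49 ± 0.1096 and 0.53 ± 0.109 (adjusted p = 0.0011 and 4.99e-04), while CDKN2A (p16) did not pass (-0.11 ± 0.155 and -0.09 ± 0.155, adjusted p = 0.667 and 0.724). The stromelysin gene MMP3 changed by -1.07 ± 0.0619 and -0.58 ± 0.0612. IGFBP3 rose by 0.33 ± 0.0578 and 0.94 ± 0.0581 and COL1A1 by 0.23 ± 0.0597 and 0.51 ± 0.0598. GDF15 passed with guide 1 (0.39 ± 0.0694) and not with guide 2 (0.06 ± 0.0707, adjusted p = 0.577). IL6 (0.18 ± 0.368 and 0.86 ± 0.337, adjusted p = 0.773 and 0.0604), MDM2, RB1, HMGB1 and GLB1 passed with neither guide.

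The p21 gene CDKN1A and HMGB2 sat near the threshold in the knockdown table. CDKN1A measured 202 ± 8.72, 225 ± 7.54 and 233 ± 11.03 CPM in sgCtrl and with guides 1 and 2, log2 changes of 0.16 ± 0.0595 (adjusted p = 0.0495) and 0.20 ± 0.0594 (adjusted p = 0.0113). The first call was lost when sgCtrl replicates 2 or 3 (adjusted p = 0.104 and 0.127), any guide 1 library (0.0657, 0.165 and 0.176) or any guide 2 library (0.075, 0.0676 and 0.0562) was left out. The second was lost without guide 2 replicate 1 (adjusted p = 0.0648). HMGB2, a chromatin protein that declines in senescence, changed by -0.40 ± 0.0657 with guide 1 (adjusted p = 1.97e-05) and -0.21 ± 0.0653 with guide 2 (adjusted p = 0.0193), a call lost without guide 2 replicate 1 (adjusted p = 0.152).

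The guides were also compared with each other, since effects of a single guide need not come from PURPL. In that contrast 1288 of 13923 genes differed (767 higher and 521 lower with guide 2), and 21 of the 45 list tests between the arms of both tables passed, 7 of them also with an estimated correlation. Members of the mitosis list lay higher with guide 2 in 23 of 34 cases and lower in 0 (27 and 0 adjusted over the list alone), with a median difference of 0.36 (adjusted p = 4.38e-21, 0.00127 with an estimated correlation). Contractile genes lay higher with guide 2 in 12 of 17 cases (13 adjusted over the list alone; median 0.36, camera adjusted p = 7.73e-19, 0.00136 with an estimated correlation) and interferon genes in 14 of 25 (18 higher and 1 lower adjusted over the list alone; median 0.22, camera adjusted p = 3.87e-12, 0.00275 with an estimated correlation). Cholesterol synthesis genes lay lower in 10 of 20 cases (13 adjusted over the list alone; median -0.28, camera adjusted p = 1.99e-10, 0.0101 with an estimated correlation) and oxidative stress genes in 9 of 20 (10 adjusted over the list alone; median -0.21, camera adjusted p = 1.50e-08, 0.00842 with an estimated correlation).

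Overexpression of PURPL was followed by a loss of interferon-stimulated transcripts and, again, of cell division transcripts. All 26 measured interferon response genes fell in both lines, with medians of -3.78 and -3.92. When all 18 libraries were scaled together, this list lay higher in Ctrl than in sgCtrl by a median of 1.66. The lines lay at -2.56 from sgCtrl, so raised levels in Ctrl could account for part of the fall. Both values also carry any difference between the experiments. MX1, an antiviral GTPase, went from 1874 ± 19.2 CPM (SD, n = 3) in Ctrl to 82.8 ± 5.22 in line 1 and 78.0 ± 2.80 in line 2. IL6, a cytokine of the senescence secretome, went from 14.9 ± 0.929 to 2.14 ± 0.252 and 2.02 ± 0.405 CPM, and MKI67 from 376 ± 16.6 to 129.8 ± 10.1 and 136 ± 14.1 CPM. In edgeR's quasi-likelihood test, 6047 of 15267 genes changed in line 1 (2978 up, 3069 down) and 5878 in line 2 (2882 up, 2996 down), or 39.6% and 38.5%. The higher mitochondrial share of the lines (4.97% to 6.24%, against 4.26% to 4.80% in Ctrl) runs alongside all gene groups that follow. At least a 2-fold change was found for 1131 genes in line 1 (328 up, 803 down) and 1105 in line 2 (310 up, 795 down).

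The lines shared 4300 of these genes with the same direction (2043 up, 2257 down), and 57 passed in opposite directions. Independent lists of these sizes, with every gene equally likely to be called, would share 562 genes up and 602 down. Simulated unchanged arms with a shared control group had 0 genes in common in 5 simulations, a count bound to lie near 0 here too. Across genes the fold changes of the lines correlated at 0.826 against a simulated 0.496. Their covariance was 0.342 against a simulated 0.0202, a difference of 0.322. Here too part of the excess may come from the shared controls.

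The interferon list passed camera in both lines, with adjusted p = 4.21e-05 and 1.20e-05 with an estimated correlation, and a value too small to be represented at the preset correlation. All 26 members also fell adjusted over the list alone. RSAD2 (viperin) went from 315 ± 8.18 to 2.56 ± 0.365 and 1.67 ± 0.484 CPM (adjusted p = 1.01e-30 and 8.86e-31), OAS1 from 189 ± 6.50 to 4.38 ± 0.542 and 6.20 ± 1.247 CPM, and IFI44L from 545 ± 13.1 to 19.96 ± 2.61 and 19.4 ± 0.194 CPM. OAS2 changed by log2 values of -3.95 ± 0.0585 and -3.88 ± 0.0587 and BST2 by -4.72 ± 0.194 and -5.21 ± 0.209. CXCL10, named here after its values were seen, had 142 counts over the Ctrl libraries, 1 in line 1, a ratio of 152 (95% counting interval 26.8 to 6040.0), and 0 in line 2, so that it was at least 43.4-fold lower there. At that bound CXCL10 still lay below the list median in line 2, so the median necessarily stayed at -3.92.

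The inflammatory secreted factors fell in 15 of 16 measured members in each line, 15 also adjusted over the list alone, with medians of -2.66 and -2.33 (adjusted p = 7.33e-24 and 1.49e-19, 5.64e-04 and 0.00141 with an estimated correlation). CXCL8 went from 17.5 ± 0.794 to 0.909 ± 0.0808 and 0.898 ± 0.339 CPM (adjusted p = 4.59e-19 and 1.20e-18), and the chemokine gene CXCL1 from 32.6 ± 5.11 to 1.49 ± 0.401 and 2.99 ± 0.649 CPM. IL6 changed by -2.79 ± 0.141 and -2.87 ± 0.146 (adjusted p = 2.52e-16 and 3.51e-16) and PTGS2 by -1.24 ± 0.0541 and -1.33 ± 0.0546. In 1 fit that scaled all 18 libraries together, the inflammatory list lay higher in Ctrl than in sgCtrl by a median of 2.05 ± 0.51 (SE over 16 genes). The lines lay at 0.015 ± 0.31 from sgCtrl, and both values also carry any difference between the experiments. Of 22 proteases, inhibitors and growth factors, 14 fell and 6 rose in line 1 and 13 fell and 4 rose in line 2 (adjusted over the list alone, 14 and 7, then 13 and 4), with medians of -0.42 and -0.44 (adjusted p = 8.04e-14 and 1.17e-11, 0.00101 and 0.00147 with an estimated correlation). MMP1 went from 597 ± 10.6 to 93.4 ± 4.63 and 94.7 ± 3.04 CPM, MMP3 changed by -1.98 ± 0.0570 and -2.24 ± 0.0583, and the urokinase gene PLAU by -2.71 ± 0.0997 and -2.31 ± 0.0979.

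The mitosis list fell in all 34 members in both lines, also adjusted over the list alone, with medians of -1.14 and -1.23 (adjusted p = 1.82e-39 and 2.78e-48, 5.64e-04 and 4.79e-04 with an estimated correlation). TOP2A went from 225 ± 5.25 to 87.9 ± 1.79 and 83.7 ± 3.296 CPM, and CENPF, a kinetochore protein, changed by -1.38 ± 0.0532 and -1.58 ± 0.0541. DNA replication genes fell in 32 and 30 of 34 cases (33 and 30 adjusted over the list alone), with medians of -0.94 and -0.81 (adjusted p = 4.69e-14 and 2.26e-11, 7.95e-04 and 0.00199 with an estimated correlation). RRM2 went from 92.0 ± 5.40 to 36.5 ± 0.883 and 47.7 ± 2.31 CPM, and CDC45, part of the replicative helicase, changed by -1.82 ± 0.127 and -1.62 ± 0.127. The contractile and TGF-beta list rose in 15 and 13 of 19 members and fell in 2 in each line (adjusted over the list alone, 15 and 14 rose and 2 fell), with medians of 0.57 and 0.32 (adjusted p = 2.42e-09 and 2.93e-05, 0.00274 and 0.0128 with an estimated correlation). CCN2, a matricellular growth factor, went from 273 ± 10.2 to 812 ± 20.7 and 500.1 ± 13.5 CPM, and the collagen-binding integrin gene ITGA11 rose by 1.16 ± 0.0509 and 0.87 ± 0.0509.

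**Figure D3:**
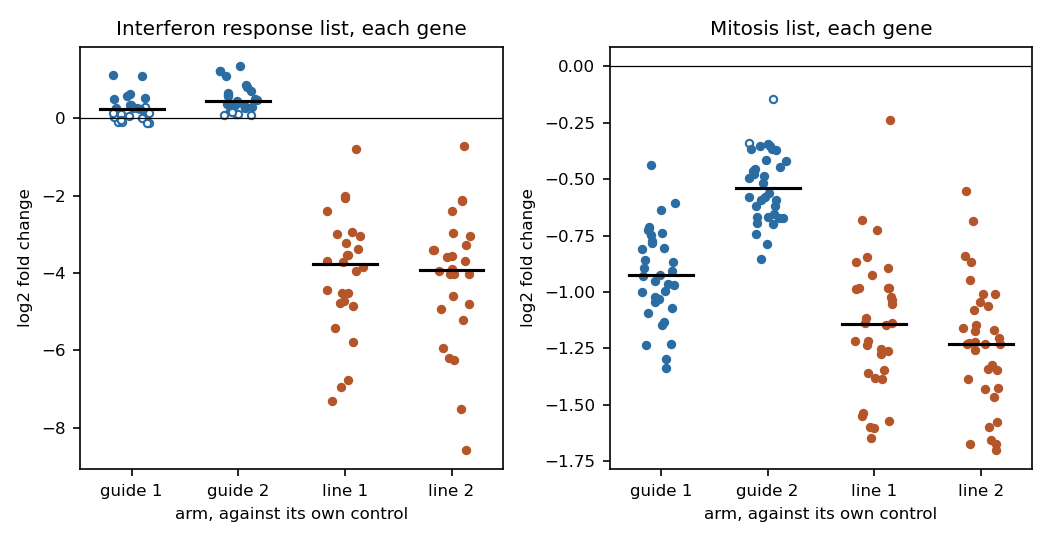
Log2 fold change (vertical axis) of each measured gene of the interferon response list (left) and the mitosis list (right) in each arm against its own control, with filled points for adjusted p below the threshold and bars for the list median. Interferon genes lie around medians of 0.25 and 0.45 with the guides and -3.78 and -3.92 in the lines, where the lowest point of line 2 is CXCL10 with 0 counts, whose fitted value is not a bound; mitosis genes lie below 0 in every arm.

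Cytosolic ribosomal protein genes rose in 25 and 30 of 36 cases and fell in 0 (26 and 30 adjusted over the list alone), with medians of 0.32 and 0.54 and adjusted p = 8.21e-06 and 2.69e-12, but adjusted p = 0.406 and 0.185 with an estimated correlation. Of these 36 genes, 19 partly overlap a same-strand gene and are uncertain. RPS14 rose by 0.48 ± 0.0609 and 0.57 ± 0.0611. Immediate early genes fell in line 1 in 11 of 20 cases and rose in 4 (12 and 5 adjusted over the list alone; median -0.55, adjusted p = 0.00133, but adjusted p = 0.0736 with an estimated correlation) and did not pass in line 2 (median -0.22, adjusted p = 0.11). FOSL1, a subunit of AP-1, changed by -2.24 ± 0.0800 and -2.02 ± 0.0799. In line 2, fibroblast identity genes rose in 11 of 15 cases and fell in 3, the same adjusted over the list alone (median 0.38, adjusted p = 0.0102, but adjusted p = 0.248 with an estimated correlation), and PDGFRB rose by 0.66 ± 0.0538. Oxidative stress genes rose in 11 of 20 cases and fell in 2 in line 2 (11 and 3 adjusted over the list alone; median 0.15, adjusted p = 0.0264, but adjusted p = 0.1 with an estimated correlation). Neither list passed in line 1 (medians 0.31 and 0.03, adjusted p = 0.44 and 0.678).

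A few list calls of the overexpression table lay close to the threshold. Lysosome genes fell in line 1 in 10 of 22 cases and rose in 2 (11 and 2 adjusted over the list alone; median -0.18, adjusted p = 0.034, but adjusted p = 0.436 with an estimated correlation), a call lost without Ctrl replicate 2 (median -0.11, adjusted p = 0.0581). In line 2 their median was -0.16 (adjusted p = 0.0687). Histone genes fell in line 1 in 8 of 12 cases, 8 also adjusted over the list alone (median -0.46, adjusted p = 0.0442, but adjusted p = 0.136 with an estimated correlation), a call lost without Ctrl replicates 1 or 2 (medians -0.44 and -0.44, adjusted p = 0.0512 and 0.0621). In line 2 their median was -0.21 (adjusted p = 0.517). Collagen and matrix genes rose in line 2 in 11 of 25 cases and fell in 5, the same adjusted over the list alone (median 0.11, adjusted p = 0.0403, but adjusted p = 0.426 with an estimated correlation). That call was lost without Ctrl replicates 1 or 3 (medians 0.11 and 0.09, adjusted p = 0.0512 and 0.0624), and in line 1 the median was 0.20 (adjusted p = 0.165).

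The remaining lists did not pass in either line. Medians in lines 1 and 2 were -0.15 and -0.09 for p53 targets (adjusted p = 0.377 and 0.742), -0.18 and -0.03 for cholesterol synthesis (0.295 and 0.678), 0.01 and 0.05 for the unfolded protein list (0.925 and 0.684), and -0.07 and -0.03 for glycolysis and hypoxia (0.44 and 0.836). They were -0.29 and -0.20 for ribosome biogenesis (adjusted p = 0.0588 and 0.249), 0.05 and -0.10 for oxidative phosphorylation (0.702 and 0.888), 0.29 and 0.32 for mitochondrially encoded genes (0.115 and 0.122), and -0.28 and -0.03 for heat shock (0.0812 and 0.512). Mean and median differed in sign for the unfolded protein list in both lines (means -0.12 and -0.15), fibroblast identity and oxidative stress genes in line 1 (means -0.07 and -0.08) and glycolysis in line 2 (mean 0.02).

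Of the single genes ranked by the mean change of both lines, the 10 lowest were NRIR, a noncoding RNA induced by interferon, RSAD2, OASL, GBP5, CMPK2, IFI27, OAS1, BST2, IFI44L and CCL5. NRIR had 1146 counts over the Ctrl libraries and 1 in line 1, a ratio of 1230.0 (95% counting interval 219 to 48400.0), and GBP5 had 342 and 3, a ratio of 122 (41.4 to 594). In line 2 they fell from 16.1 ± 1.15 and 4.88 ± 0.459 CPM to 0.0896 and 0.0955 CPM. Among the highest, MGP, an inhibitor of calcification, went from 10.4 ± 1.5 to 94.8 ± 3.40 and 49.8 ± 2.17 CPM (adjusted p = 2.11e-24 and 4.38e-20), and WNT2, a secreted growth factor, from 4.18 ± 0.973 to 15.5 ± 0.635 and 21.4 ± 1.13 CPM. GPR78, SLA, TM4SF20, GDF7, RGS7BP, AADACL4, SORBS2 and CX3CR1 rose by log2 changes of 1.24 to 3.28.

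In the senescence panel, LMNB1 fell from 26.5 ± 2.89 to 10.7 ± 0.816 and 11.2 ± 1.35 CPM (adjusted p = 6.26e-12 and 2.87e-11), and HMGB2 changed by -0.73 ± 0.0645 and -0.74 ± 0.0648. MKI67 changed by -1.54 ± 0.0666 and -1.47 ± 0.0666, CCNB1 by -1.05 ± 0.0685 and -1.23 ± 0.0701 and MCM2 by -1.45 ± 0.123 and -1.23 ± 0.123. IL1B fell from 14.6 ± 2.15 to 1.75 ± 0.227 and 2.72 ± 0.520 CPM and GDF15 from 5.79 ± 0.866 to 1.28 ± 0.150 and 1.59 ± 0.210 CPM. COL1A1 rose by 0.60 ± 0.0553 and 0.47 ± 0.0553 and the ubiquitin ligase gene MDM2 changed by -0.20 ± 0.0502 and -0.38 ± 0.0506. IGFBP3 rose by 0.18 ± 0.0516 in line 1 (adjusted p = 0.00602) and fell in line 2 (-0.26 ± 0.0517, adjusted p = 1.65e-04). GLB1, which encodes the enzyme of senescence-associated beta-galactosidase staining, passed in line 1 (-0.31 ± 0.0756, adjusted p = 0.00149) and not in line 2 (-0.16 ± 0.0758, adjusted p = 0.097). CDKN2A, CDKN2B, RB1 and HMGB1 passed in neither line.

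The p21 gene moved little. CDKN1A measured 77.8 ± 3.74, 69.9 ± 7.37 and 66.7 ± 3.85 CPM in Ctrl and lines 1 and 2, log2 changes of -0.15 ± 0.0659 (adjusted p = 0.0649) and -0.23 ± 0.0666 (adjusted p = 0.00791), the latter lost without line 2 replicate 3 (adjusted p = 0.0563).

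The lines differed from each other in 1888 of 15267 genes (943 higher and 945 lower in line 2), and PURPL itself was lower in line 2. Contractile genes lay lower in line 2 in 7 of 19 cases and higher in 0 (8 and 0 adjusted over the list alone; median difference -0.22, adjusted p = 6.03e-05, 0.0222 with an estimated correlation). Oxidative stress genes lay higher in 9 of 20 cases and lower in 2 (9 and 5 adjusted over the list alone; median difference 0.17, adjusted p = 1.43e-04, 0.0239 with an estimated correlation). The aldo-keto reductase gene AKR1C3 was among the genes higher in line 2 (1.76 ± 0.142) and the muscle ankyrin repeat gene ANKRD1 among those lower (-1.72 ± 0.256).

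Knockdown and overexpression were then compared, which asks whether the 2 manipulations moved the same genes in opposite directions. Among 13638 genes tested in both tables, 354 passed in both guides and both lines with opposite directions, 192 up on knockdown and down on overexpression and 162 the other way, where independent lists would give 306 (144 and 162). In contrast, 657 passed with the same direction in all 4 contrasts (202 up, 455 down), where independent lists would give 308 (133 and 175). Those expected counts treat every gene as equally likely to be called. Genes that are easier to call in both tables would raise the observed counts above them, which was not tested. Across genes, which are not independent replicates, the mean fold changes of knockdown and overexpression had a Pearson correlation of 0.0528 (Spearman 0.0869), whose sign turned with no filter (-0.0134) and with DESeq2 (-0.00569). In the joint edgeR fit, the knockdown effect differed from the overexpression effect for 5102 of 15166 genes (2730 higher and 2372 lower on knockdown, and 2547 and 2558 with DESeq2's size factors). Apart from the joint fit, which scaled all 18 libraries together, the tables were normalized separately, each with its own control.

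Genes with opposite calls included EPB41L3, a membrane skeleton protein, at 8.28 ± 1.66 CPM in sgCtrl and 34.8 ± 4.43 and 43.1 ± 4.56 CPM with the guides, and at 33.1 ± 1.98 CPM in Ctrl and 11.2 ± 0.818 and 13.3 ± 1.64 CPM in the lines. EPB41L3, and likewise CXCL8, lay higher in Ctrl than in sgCtrl, and the lines lay nearer to sgCtrl than to Ctrl. A raised level in Ctrl could therefore account for most of their fall, and levels across the tables carry any difference between the experiments. The copine gene CPNE8 rose by 1.94 ± 0.3001 and 2.28 ± 0.288 with the guides and changed by -1.97 ± 0.205 and -2.50 ± 0.225 in the lines. CXCL8, ASPA, LAMP3, GBP1P1 and the complement gene C3 went the same way, C3 by 1.62 ± 0.118 and 1.21 ± 0.122 and then -3.41 ± 0.0706 and -2.22 ± 0.0655. CXCL5 and RTP4 were also ranked here, but the CXCL5 call with guide 2 (1.61 ± 0.565, adjusted p = 0.0359) was lost without any sgCtrl library (adjusted p = 0.0959, 0.0807 and 0.0709) and without guide 2 replicates 1 or 3 (0.0724 and 0.185). The RTP4 call with guide 1 (1.35 ± 0.474, adjusted p = 0.0361) was lost without sgCtrl replicate 2 (0.216) or guide 1 replicates 2 or 3 (0.0548 and 0.219, adjusted p). Genes with the same direction in all 4 contrasts included DACT1, a regulator of Wnt signalling (1.72, 2.30, 1.78 and 1.61), and the apoptosis gene BMF (1.84, 1.52, 1.52 and 1.71), both up. CNGA3 (-2.42, -2.52, -2.27 and -2.44) and TMEM158 (-1.54, -2.38, -2.10 and -1.64) were down. KRT15 was also ranked there, but its line 1 call (-1.49 ± 0.460, adjusted p = 0.0104) was lost without Ctrl replicate 3 (adjusted p = 0.0751) or a line 1 library (0.0549).

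**Figure D4:**
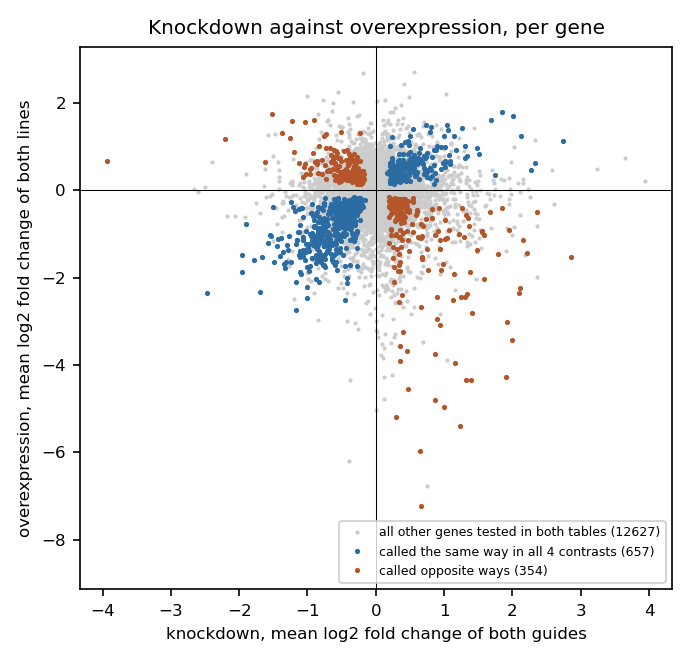
Mean log2 fold change of both lines against Ctrl (vertical axis) and of both guides against sgCtrl (horizontal axis) for each of 13638 genes tested in both tables. Colour marks the 657 genes called in the same direction in all 4 contrasts and the 354 called in opposite directions, and the correlation across all genes is 0.0528.

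Markers of other cell types were looked up as well. Keratinocyte markers did not pass in the lines (medians -0.10 and 0.08, adjusted p = 0.992 and 0.925, with a mean of -0.09 in line 2), nor did endothelial markers (medians -0.63 and -0.00249, adjusted p = 0.682 and 0.684). Endothelial markers in the knockdown table, and melanocyte and immune cell markers in either table, had fewer than 5 measured genes and were not tested as lists; their genes below were chosen after their values were seen. Of the endothelial genes, TEK fell with guide 1 (-1.37 ± 0.241, adjusted p = 6.08e-05) and in both lines (-0.72 ± 0.205 and -1.51 ± 0.229). Of the melanocyte genes, MITF, a transcription factor that fibroblasts also express, rose with guide 1 (0.36 ± 0.0730, adjusted p = 3.50e-04) and in both lines (0.47 ± 0.0572 and 0.46 ± 0.0576), while PAX3 passed in no contrast. TYRP1 had 4 counts over the Ctrl libraries and 1 in line 1, a ratio of 4.28 (95% counting interval 0.423 to 211), and measured 0.581 ± 0.148 CPM in line 2 (adjusted p = 6.42e-04). Of the immune cell genes, CD74, which interferon also induces, fell in both lines (-1.66 ± 0.411 and -1.55 ± 0.419) and PTPRC passed in no contrast.

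Several genes named above partly overlap an annotated neighbour on the same strand, and their counts are uncertain. These are CNGA3, MBP, SYT7, KCNIP4, UHRF1, TOP2A, IFIT2, TXNRD1, LDHA, GPR78, SLA, RGS7BP, SORBS2, C3, DACT1, KRT15, MDM2, RB1, HMGB1, GLB1, GDF15 and TEK.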

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

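Of the tests below, the one that left out single controls for the mitosis list, the one on faster-dividing control cultures and the comparison of cell division and inflammatory genes between the controls were chosen only after the result was seen. The differences in the next 3 paragraphs were brought here by a test of the difference between groups, edgeR's quasi-likelihood test for genes and camera for lists, and are log2 values.

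The guides differed in 1288 genes, the lines in 1888, and the knockdown effect differed from the overexpression effect in 5102. Guide 2 minus guide 1 gave list medians of 0.359 for mitosis, 0.364 for contractile genes, 0.221 for interferon response, -0.276 for cholesterol synthesis and -0.214 for oxidative stress, all past the threshold also with an estimated correlation. The medians of 0.102 for the unfolded protein list, -0.0866 for lysosome, -0.106 for ribosomal proteins, -0.246 for histones and -0.0958 for fibroblast identity were lost with it (adjusted p = 0.386, 0.337, 0.586, 0.0624 and 0.154 with an estimated correlation).

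Line 2 minus line 1 gave medians of -0.217 for contractile genes and 0.174 for oxidative stress, both past the threshold also with an estimated correlation. The medians of 0.294 for inflammatory factors, 0.12 for DNA replication, -0.0664 for mitosis, 0.0922 for glycolysis and 0.179 for ribosomal proteins were lost with it (adjusted p = 0.0634, 0.154, 0.249, 0.202 and 0.372 with an estimated correlation). So were those of 0.253 for immediate early genes, 0.096 for heat shock, 0.327 for histones and 0.175 for fibroblast identity (adjusted p = 0.0624, 0.202, 0.0624 and 0.136 with an estimated correlation).

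Of single genes, guide 2 minus guide 1 was 0.333 for MKI67, 0.437 for CCNB1, 0.498 for MMP3, -0.33 for GDF15, 0.608 for IGFBP3 and 0.283 for COL1A1. The lowest differences were KC6 at -1.94, VAV3 at -1.81, HCLS1 at -1.55, ADAM23 at -1.42 and C3orf80 at -1.42, and the highest TNFSF15 at 3.10, NXF3 at 2.83, KISS1 at 2.45, PALMD at 2.28 and ACKR3 at 2.26. Line 2 minus line 1 was -0.499 for PURPL, -0.177 for MDM2, 0.609 for IL1B, -0.267 for MMP3 and -0.438 for IGFBP3. The lowest were KRT4 at -3.28, LINC01934 at -2.70, PLCE1-AS1 at -2.30, FOLR3 at -1.88 and ANKRD1 at -1.72, and the highest EGFL6 at 2.38, ADH1B at 2.12, CAVIN4 at 1.84, AKR1C3 at 1.76 and RSPO3 at 1.67. HCLS1, LINC01934, FOLR3, EGFL6 and ADH1B partly overlap a same-strand neighbour and are uncertain.

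The fall of interferon genes in both lines does not rest on a single control library, since the list median stayed at or below -3.74 with each left out. A raised interferon response in the Ctrl cultures is harder to set aside. In 1 fit that scaled all 18 libraries together, Ctrl lay above sgCtrl by a list median of 1.66 ± 0.13 (SE over 26 genes, 23 of them above 0). The lines differed from sgCtrl by a median of -2.56 ± 0.25. The inflammatory factors lay higher in Ctrl than in sgCtrl by 2.05 ± 0.51 (14 of 16 above 0) and the lines level with sgCtrl (0.015 ± 0.31), so raised levels in Ctrl could account for all of their fall. For interferon genes raised controls could account for part of the fall but leave the lines below sgCtrl as well, and a difference between the experiments cannot be told from an effect of PURPL.

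The mitosis list was lower after knockdown and after overexpression, and the highest median with 1 control library left out was -0.702. Overlapping gene spans do not explain it, as the 29 members with no same-strand overlap had medians of -0.743 (knockdown) and -1.23 (overexpression). Control cultures of both tables that divided faster for a reason other than PURPL could produce it. In the fit that scaled all 18 libraries together, the median of Ctrl minus sgCtrl was -0.0356 ± 0.092 for mitosis but -0.381 ± 0.12 for DNA replication (7 of 34 genes above 0). Lines minus sgCtrl lay at -1.32 ± 0.071 and -1.4 ± 0.17. These values also carry any difference between the experiments, and with 1 control group per table they exclude nothing. The biological reading, that a change of PURPL in either direction lowers division, was not separated from this.

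Regrouping the libraries asked whether other groupings of the same libraries give counts as high. For single contrasts the 10 possible splits are too few to tell, with the real split the only 1 as large in each case: 3417 (highest other 0) for guide 1, 3393 (1) for guide 2, 6047 (0) for line 1, 5878 (0) for line 2, 1288 (0) between guides and 1888 (0) between lines. Over 40 regroupings the joint contrast was highest with the real grouping (5102, highest other 357, median of the others 0, 1 as large). Regroupings mix groups that differ, which widens the spread and lowers their calls, so a higher real count was likely in advance. Shuffling libraries that may be technical replicates also cannot exclude chance between cultures. For the genes shared by both guides (2076, highest other 1), by both lines (4300, 97) and those with opposite calls (354, 0), each with 1 as large, the regroupings cannot tell, since they call few genes in any contrast and so leave little overlap to compare. The 25 list calls with an estimated correlation were more than in any other regrouping (highest other 5, 1 as large), but the limits given for the joint contrast apply to them too. Chance cannot be excluded for the 41 at the preset correlation (highest other 44, 3 as large). Nor can it be for the correlation between knockdown and overexpression of 0.0528, since 13 of the 40 lay as far from 0 (highest other 0.107).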

How the results depend on the processing

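No called gene or list changed its direction under any alternative, while the correlation between the tables, which has no test, changed its sign under 2. With DESeq2's size factors 659 of 660 values of named genes kept their call, with no filter beyond 1 count 647, and with DESeq2's Wald test 640. Leaving out 1 library kept 5704 of 5938, with 141 weaker, 25 stronger and 68 uncalled values of the other sign, and 765 of 810 list results. The ranges with 1 library left out were 2624 to 3671 genes (guide 1), 2591 to 3497 (guide 2), 5132 to 6243 (line 1), 5073 to 5800 (line 2), 881 to 1755 (between guides), 1259 to 2045 (between lines), 1618 to 2266 (shared by guides), 3661 to 4225 (shared by lines), 265 to 395 (opposite), 558 to 665 (same in all 4), 4549 to 5105 (joint), 0.041 to 0.0597 (correlation) and 39 to 43 lists. PURPL ranged from -2.47 to -2.23, -2.14 to -1.93, 1.37 to 1.46 and 0.87 to 0.98. A 2-fold threshold left 481, 432, 1131 and 1105 genes for guides 1 and 2 and lines 1 and 2, 164 between guides, 181 between lines, 211 shared by guides, 736 by lines, 23 opposite, 29 the same in all 4 and 1143 in the joint contrast, as a stricter threshold must leave fewer. Genes with no same-strand overlap, an alternative chosen after seeing the data, gave 3924 (line 1) and 3855 (line 2), with fewer genes tested (10328). The correlation between tables was -0.0134 with no filter, -0.00569 with DESeq2 and, chosen after seeing the data, 0.0737 without the interferon list; the cause was not tested. Of the 41 list calls 25 held with an estimated correlation, which allows for members that vary together, while the rotation test called 61 of 90 and the fit with no filter 55 of 100. The replicate numbers gave no sign of pairing the libraries of the knockdown table, judged by deviations of log2 CPM from the group mean. Across groups, these deviations correlated at -0.0888 to 0.0386 between same-numbered libraries and at -0.0835 to 0.114 between other pairs. By the same measure, 0 of 9 libraries matched best with its own number. With the number as a block, guides 1 and 2 gave 3250 and 3217 genes and 1204 between them. Because 5 columns of the overexpression table carry no number, no block was fitted there. Rare transcripts are limited by depth, which was lower in the knockdown table, but recovery by expression level was not tested.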

Other observations

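The lists of BMP, ERK and antigen presentation genes were added only after ID1, ID2, ID4, DUSP4 and the interferon list had been seen, and their tests were run on other genes. Some of these, such as SMAD7 and FOSL1, also belong to the fixed contractile or immediate early lists. All were measured in the same libraries, so these tests are not independent of what had been seen. Besides ID1, the genes ID2 and ID4, inhibitors of differentiation chosen here after their values were seen, rose with both guides (ID2 2.18 ± 0.0683 and 2.29 ± 0.0683, ID4 2.08 ± 0.241 and 2.24 ± 0.236). Of 10 other targets of BMP signalling, 6 rose with both guides and 0 fell, with a median of 1.31 ± 0.26 (SE over genes; camera adjusted p = 4.69e-04 with an estimated correlation for each guide). Of these genes, with examples also chosen after their values were seen, ID3 rose by 1.85 ± 0.121 and 2.1005 ± 0.118, SMAD6 by 1.76 ± 0.116 and 2.14 ± 0.112, ATOH8 by 1.63 ± 0.101 and 2.05 ± 0.0985, and the BMP antagonist gene NOG by 1.45 ± 0.209 and 1.30 ± 0.213. In the lines the BMP list did not pass (medians -0.0453 and 0.123, camera adjusted p = 0.841 and 0.573). The knockdown data may therefore hold raised BMP signalling after knockdown of PURPL, which no protein measurement here tests. SMAD6 partly overlaps a same-strand neighbour and is uncertain.

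DUSP4, a phosphatase induced by ERK that was also chosen after its values were seen, was lower with both guides (-1.49 ± 0.115 and -1.60 ± 0.117). Of 12 other ERK targets 1 rose and 3 fell with both guides, and the list median of -0.0519 ± 0.087 (SE; camera adjusted p = 0.463 and 0.607) cannot tell whether ERK signalling changed. In the lines the same list fell in 9 and 8 of 12 members (medians -0.448 and -0.361, camera adjusted p = 8.46e-06 and 1.35e-04, but adjusted p = 0.0594 and 0.0762 with an estimated correlation). In the overexpression lines, 13 of 15 genes of antigen presentation by MHC class I fell in both lines along with the interferon genes, with a median of -0.914 ± 0.19 (SE; camera adjusted p = 4.69e-04 with an estimated correlation in each line). With the guides that list did not pass (medians 0.0213 and 0.06, camera adjusted p = 0.841 for each). Among examples chosen after their values were seen, HLA-B changed by -1.72 ± 0.0630 and -1.77 ± 0.0636, TAP1 by -1.95 ± 0.0950 and -1.93 ± 0.0964, and B2M by -1.09 ± 0.0522 and -1.30 ± 0.0525, of which HLA-B partly overlaps a same-strand neighbour and is uncertain. Since interferon also induces these genes, a raised interferon response in the controls could lower them in the same way.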
